A study of Mus musculus with 12 samples.

How the data were processed

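RNA was measured in wild-type mouse embryonic fibroblasts (MEFs) that carried either a guide RNA against the p53 response element of Pvt1 or a non-targeting control guide, untreated or after 24 h in 0.5 µM doxorubicin. The series holds 12 samples in 4 groups of 3 replicates. The table used here holds the 6 doxorubicin-treated samples of 2 groups. The 6 untreated samples were not analysed here, so that 4 of the 5 comparisons planned before the data were examined (both doxorubicin effects, the guide effect without doxorubicin and the interaction) could not be made.

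Libraries were prepared from polyadenylated RNA with a strand-specific TruSeq mRNA kit, per the labels' protocols. TopHat2 2.0.14, StringTie 1.2.4, HTSeq 0.6.1, edgeR 3.22.3 and the genome build mm10 were used, per the submitters' processing notes, which give no role or order for the tools and no strand setting. The deposited values used here are CPM (reads scaled to a common library size) per gene and library, made with edgeR per the file headers. The deposited CPM of a library summed to between 989489 and 1011369, so the divisor was a scaled library size and not the plain total. The same table holds the authors' log2 fold change and average log2 CPM, deposited per the file headers for the guide effect under doxorubicin. It also holds the authors' p-value and false discovery rate, deposited for the same comparison without the name of the test. The 6 per-sample columns of pseudo-counts in the table were not used. How replicates were grown or paired, how genes were filtered and where the guide binds are not stated in the sources used here.

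The table has 16427 entries, of which 2 collect reads assigned to no gene (ambiguous reads and reads outside genes) and were removed. Ambiguous reads made up 0.543%, 0.784% and 1.36% of the control libraries and 1.58%, 0.926% and 1.16% of the libraries with the guide against the response element, in replicate order. Reads outside genes made up 8.24%, 8.06% and 8.33% of the control libraries and 8.66%, 8.41% and 8.94% of the others. The deposited CPM still carry both in their divisor and were not rescaled. Of the 16425 gene symbols, 15866 matched GENCODE M21, 10 matched RefSeq only and 549 matched neither. The symbols are in capitals and were written here in mouse style, 22 had been turned into dates, and 1 was listed more than once. The lowest total of a listed gene over the 6 libraries was 52 reads. Values are per gene, so isoforms of Pvt1 were not separated.

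Each CPM value was divided by the worth of 1 read in its library, taken from the steps between low values. All values in genes came out whole within 0.01 reads. The recovered reads in genes ranged from 50091418 to 66132317 per library.

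The main test was limma 3.58.1 with trend and robust empirical Bayes on log2(CPM + 0.5), on the 14440 genes with at least 0.5 CPM in at least 3 libraries, with a threshold of 0.05 on the Benjamini-Hochberg adjusted p. This fit had 4 residual degrees of freedom, where the plan for 12 samples had 8. Fold changes are the guide against the response element over the control guide. Whether equal replicate numbers pair the libraries was decided by a rule fixed before the data were examined. Deviations of libraries from their group means correlated at 0.869, 0.739 and 0.817 for equal numbers, across genes, which are not independent replicates, and at most at 0.203 for other pairs, so the numbers pair the libraries. Replicate number held 86.9% of the variance, the guide 4.59% and the residual 8.50%. The guide's share is thus not by itself a sign of a guide effect. The alternative fixed beforehand with replicate number as a block (2 residual degrees of freedom) is therefore printed beside the main test, called the blocked fit below. Copied libraries were looked for by chi-square per gene, which was 24.1 or more between replicates of a group and 5.78 or more between guides, far above sampling noise of the same RNA.

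Gene lists fixed before the data were examined (19, of which 16 had at least 5 tested members) were tested with camera at a preset correlation of 0.01, and with an estimated correlation and fry beside it. Tested list members were also adjusted over the list alone. Named genes are Pvt1, Myc, Cdkn1a, Mdm2 and Trp53, then the genes past the threshold with a mean of at least 5 CPM and no overlap between groups or, if none passed, the 3 with the smallest p on each side, and up to 4 members per list with the smallest p. Lists of other cell types and of mitochondrially encoded genes are given by counts and by their most abundant members. Pvt1 and Myc also had an exact permutation test and an exact sign-flip test within pairs, both two-sided.

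Alternatives were quantile normalization, median centring, no filter, a mean of at least 5 CPM, pseudocounts of 1 and 0.1, limma without trend, edgeR 4.0.16 quasi-likelihood tests on the recovered reads, a threshold of 0.01, a fold of at least 2, the block, and each library left out. DESeq2 1.42.0 on the recovered reads and combinations of the block with another choice were added after seeing the data. Computations ran in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

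The tests were checked on simulated reads for this comparison with known changes, drawn with gene-specific dispersion and the libraries' depths (14614 genes in the limma fits). Without the block, limma recovered 0% of 67 genes changed 1.25-fold, 13.6% of 66 changed 1.5-fold and 60.9% of 64 changed 2-fold, with 0 false among 48 calls. With the block it recovered 58.2%, 80.3% and 95.3%, and 14 of 168 calls were false. A list of 30 genes shifted by 0.1 on the log2 scale gave a camera p of 1.01e-05, and 0 of 20 unshifted lists passed. With an estimated correlation the same shifted list gave p = 0.00885, and 0.0869 in the blocked fit, where it was missed. In reads simulated with a trended dispersion the blocked fit with an estimated correlation gave 0.0314. Genes were simulated independently of each other, so these checks could not show false list calls that come from correlation between genes. In the measured libraries the estimated correlation of the ribosome biogenesis list was 0.427, and 0.0996 in the blocked fit.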

Results

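Gene expression was measured in wild-type mouse embryonic fibroblasts (MEFs), cells cultured from mouse embryos. The cells carried a guide RNA against the p53 response element of Pvt1, a DNA site bound by the transcription factor p53, or a non-targeting control guide. The 6 libraries described here came from MEFs treated for 24 h with 0.5 µM doxorubicin, a drug that damages DNA and activates p53, with 3 replicates per guide. The libraries held 52445969, 53078389 and 61550435 reads in genes with the control guide and 59572326, 50091418 and 66132317 with the guide against the response element. Levels are given in CPM, reads scaled by the authors to a common library size. Untreated MEFs of the same series, and the comparisons that need them, were not analysed here.

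The comparison asked how RNA levels after doxorubicin differ when the response element in Pvt1 is targeted. Whether the differences depend on p53 activation cannot be told without the untreated libraries. Pvt1, a long noncoding RNA gene, stood at 13.4 ± 2.61 CPM with the control guide and at 6.46 ± 1.40 CPM with the guide against its response element (SD, n = 3 each), 0.483 times the control mean. Myc, which encodes a growth-promoting transcription factor, stood at 30.4 ± 4.55 CPM and 48.6 ± 5.16 CPM (SD, n = 3 each), 1.60 times the control mean. Genes of ribosome biogenesis lay slightly but widely higher, with 29 of 30 above the control level and a median log2 fold change of 0.08. Known p53 target genes had no common direction, with 26 of 48 higher and 22 lower.

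Pvt1 (ENSMUSG00000097039.8) lies on chromosome 15 from 62037986 to 62378096, and Myc (ENSMUSG00000022346.15) from 61985391 to 61990374, in mm10 coordinates from GENCODE M21. Both are on the plus strand and 47.6 kb apart. Pvt1 was lower in 3 of 3 pairs of libraries with equal replicate numbers, at 0.491, 0.507 and 0.448 times its partner. Myc was higher in 3 of 3 pairs, at 1.52, 1.80 and 1.51 times its partner. No Pvt1 or Myc value of one guide overlapped those of the other. Pvt1 values rested on 331 to 946 reads per library and Myc values on 1583 to 3915.

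**Figure D1:**
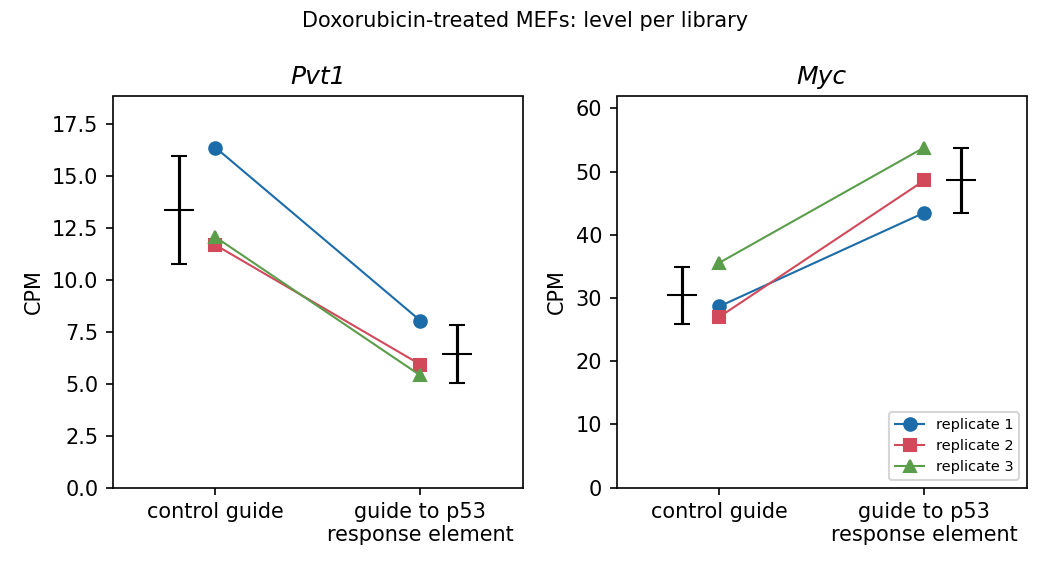
Level of Pvt1 and Myc in CPM in each doxorubicin-treated library, with lines joining libraries of equal replicate number and bars for the mean and SD of 3 replicates. Pvt1 averaged 13.4 CPM with the control guide and 6.46 CPM with the guide against the response element, and Myc 30.4 and 48.6 CPM.

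The log2 fold change was −0.999 for Pvt1 (SE 0.188) and 0.67 for Myc (SE 0.127), and neither passed the threshold over all 14440 genes in limma without a block (adjusted p = 1.0 for both). Adjusted over the list alone, among the 11 tested genes near Myc and Pvt1, both passed in the same fit (limma adjusted p = 0.0083 for both). In the blocked fit Pvt1 fell (SE 0.0717, limma adjusted p = 1.40e-04) and Myc rose (SE 0.0532, limma adjusted p = 5.49e-04) over all genes, and limma without trend lost both calls there (adjusted p = 0.249 and 0.835). Two-sided exact permutation tests gave p = 0.10 for each gene, the smallest that 3 against 3 allows, and exact sign flips within pairs gave p = 0.25, also the smallest possible. The other list members near the locus included Fam84b (log2 fold change 0.14) and Adcy8 (−0.26), which passed neither fit, and camera gave no call for the list (adjusted p = 0.835, and 0.703 in the blocked fit).

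Over all genes, limma without a block called 0 genes, with 50 at an unadjusted p under 0.05 where 722 are expected by chance. In the same way edgeR called 0 (82 unadjusted, 821 expected). DESeq2 called 1 (38 unadjusted, 821 expected), which was Pvt1 (log2 fold change −1.05, adjusted p = 0.0179). Differences between replicates stay in the error of these fits, so the low counts do not show that few genes changed. The authors' deposited table has 0 genes under a false discovery rate of 0.05. Its lowest rate is 0.224, shared by Pvt1 (log2 fold change −1.05) and Myc (0.68), which have the smallest p there. That table has 28 genes at an unadjusted p under 0.05 and a median of 0.786, so it too leans to high p. The genes with the smallest p on the higher side after Myc were Elac2, a tRNA-processing enzyme (28.0 and 32.5 CPM, log2 fold change 0.21), and Gm5805 (0.488 and 0.847 CPM, 0.45). On the lower side after Pvt1 they were BC051226 (1.82 and 1.2 CPM, −0.45) and Gsdmd, which encodes a pore-forming protein of inflammatory cell death (12.2 and 10.1 CPM, −0.26). None of these passed the threshold in either fit.

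The blocked fit called 5 genes, with 965 at an unadjusted p under 0.05 where 722 are expected by chance. The number called was not stable and rose when a replicate was left out, as given further below. All 5 were also called by edgeR and by DESeq2 with the same block. Beside Pvt1 and Myc these were 3 genes chosen after their values were seen. Aqp1, a water channel, fell from 155 ± 101 to 123 ± 79.6 CPM (SD, n = 3 each; log2 fold change −0.33, limma adjusted p = 0.00173). S100a4, a calcium-binding protein, fell from 193 ± 30.6 to 155 ± 19.1 CPM (SD, n = 3 each; −0.31, limma adjusted p = 0.0107). Adcyap1, the gene of the neuropeptide PACAP, fell from 5.80 ± 4.12 to 3.28 ± 2.12 CPM (SD, n = 3 each; −0.69, limma adjusted p = 0.0388). Each was lower in 3 of 3 pairs, although the difference was smaller than the SD of either guide for Aqp1 and smaller than that of the control guide for Adcyap1. DESeq2 with the block called 1 further gene. All 5 calls were lost in the blocked fit by limma without trend (adjusted p = 0.249 for Pvt1 and 0.835 for Myc, Aqp1, S100a4 and Adcyap1), and that of Adcyap1 also with a pseudocount of 1 (0.0505) or median centring (0.0532; range over its alternatives 5.39e-05 to 0.835).

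**Figure D2:**
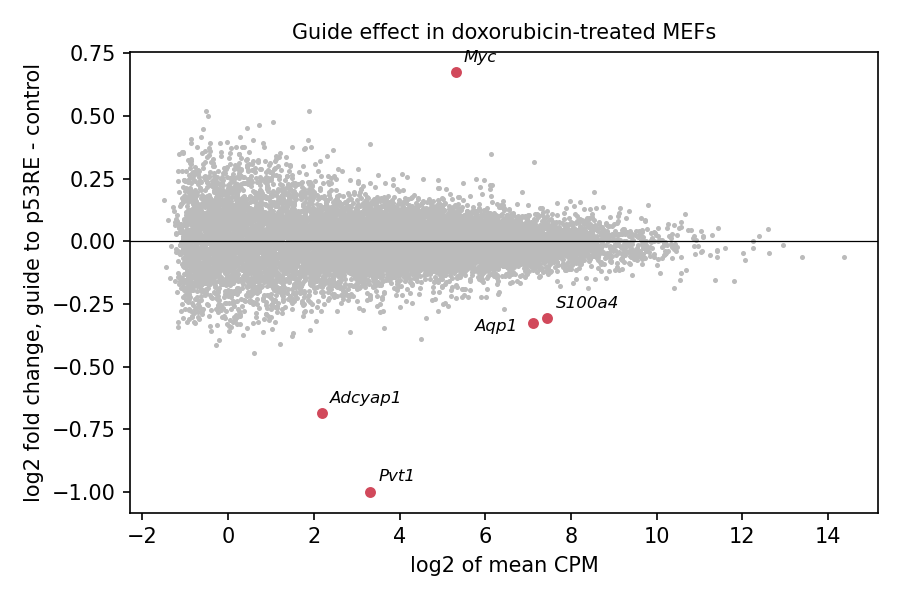
Log2 fold change of each tested gene, guide against the response element minus control guide, over log2 of its mean CPM, with the 5 genes called in the blocked fit in red. Pvt1 lies lowest at −0.999 and Myc highest at 0.67.

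The p53 pathway itself differed little between guides under doxorubicin. Cdkn1a, the p53-induced inhibitor of the cell cycle, stood at 1334 ± 134 and 1395 ± 165 CPM (SD, n = 3 each; log2 fold change 0.06, SE 0.120). Mdm2, the p53-induced ligase that degrades p53, stood at 584 ± 54.2 and 607 ± 77.8 CPM (SD, n = 3 each; 0.05, SE 0.122). Trp53, the p53 gene, stood at 160 ± 16.6 and 171 ± 4.37 CPM (SD, n = 3 each; 0.09, SE 0.0845). Among the 48 measured p53 target genes, 0 passed in limma with or without the block, over all genes or adjusted over the list alone, and camera gave an adjusted p of 0.875. The smallest p were those of Rrm2b (−0.11), Pmaip1 (474 and 428 CPM, −0.15), Foxo3 (0.06) and Prkab1 (0.07).

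Ribosome biogenesis genes were the list with the smallest p. Of 30 measured genes, 29 lay higher and 1 lower, 20 were higher in all 3 pairs, and the medians within pairs were 0.10, 0.08 and 0.11. The list rose by camera with the preset correlation (adjusted p = 2.24e-15), but not with an estimated correlation (adjusted p = 0.971, and 0.356 in the blocked fit). Adjusted over the list alone, 0 genes passed without the block and 9 rose in the blocked fit. These included Dkc1, the RNA pseudouridine synthase dyskerin (10.2 ± 1.01 and 12.3 ± 0.333 CPM, SD, n = 3 each; log2 fold change 0.27), Wdr12 (35.3 and 39.6 CPM, 0.17), Nolc1 (56.4 and 61.6 CPM, 0.13) and Wdr43 (49.8 and 54.9 CPM, 0.14). No member passed over all genes, and no list passed fry, where this list had an adjusted p of 0.417 in the blocked fit. Other ways of parting each pair of libraries swap the guides in pair 3, in pair 2 or in pairs 2 and 3. They called 4, 7 and 6 lists at the preset correlation, against 4 for the real guides in the blocked fit. Each still holds part of the guide contrast, so these counts are not free of a guide effect.

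Myc target genes of metabolism and growth showed a smaller difference, with 24 of 30 higher, 6 lower and a median of 0.04. The list rose by camera with the preset correlation (adjusted p = 2.97e-04, and 4.47e-05 in the blocked fit). It was not called with an estimated correlation (adjusted p = 0.971, and 0.356 in the blocked fit). Without the block, the call was lost without control replicate 1 (0.346) or replicate 3 of the other guide (0.308), which breaks a pair. In the blocked fit at the preset correlation, camera adjusted p with a replicate left out ranged from 2.37e-06 to 0.0169. Adjusted over the list alone, 0 genes passed without the block, and in the blocked fit Gart of purine synthesis (0.16), Srm, the spermidine synthase (0.18), and the translation factor gene Eif5a (0.14) rose. Shmt2 (0.10) did not pass.

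**Figure D3:**
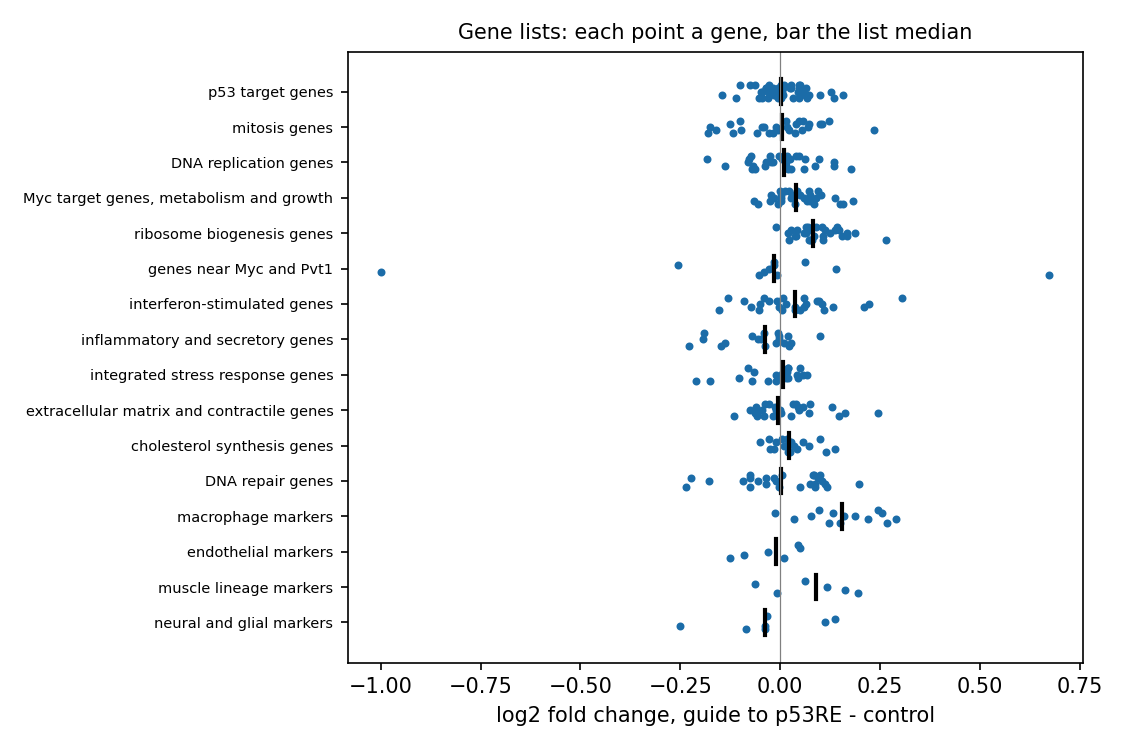
Log2 fold change of each tested member of the 16 tested gene lists, guide against the response element minus control guide, with a bar at the list median. The median was 0.08 for ribosome biogenesis genes, 0.04 for Myc target genes and 0.00 for p53 target genes.

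The inflammatory and secretory genes lay lower in 14 of 19 cases. The list was not called by camera without the block (adjusted p = 0.782), and fell in the blocked fit (adjusted p = 0.0243) but not with an estimated correlation there (adjusted p = 0.917). That call was also lost with quantile normalization (0.0647) and without replicate 2 (0.304) or replicate 3 (0.189). Vcam1 (−0.15), Mmp3 (−0.14), Cxcl5 (−0.19) and Tnfaip3 (−0.07) did not pass. Adjusted over the list alone, 0 genes passed without the block, and in the blocked fit the matrix metalloproteinase genes Mmp13 (−0.19) and Mmp10 (−0.23), chosen after their values were seen, fell. Of 23 genes of the integrated stress response, 13 lay higher and 10 lower (camera adjusted p = 0.835). Among them Nupr1, a stress-induced nuclear protein, fell from 84.3 to 72.9 CPM in the blocked fit adjusted over the list alone (log2 fold change −0.21), but did not pass there over all genes (adjusted p = 0.254) nor without the block. The members Atf5 (−0.10), Ddit4 (0.07) and Ddit3 (−0.07) did not pass either fit.

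Genes of cell division and DNA synthesis gave no call in either fit of the 6 libraries. With a replicate left out, camera in the blocked fit did call mitosis genes (adjusted p down to 0.00232). It also called extracellular matrix genes (down to 4.83e-04) and cholesterol synthesis genes (down to 0.00271). The direction for mitosis and extracellular matrix genes depended on the replicate left out. Mitosis genes were split 14 to 14 (Birc5 −0.18, Kif11 −0.18, Kif2c −0.16, Ndc80 −0.13; camera adjusted p = 0.835), with pair medians of 0.14, −0.25 and 0.03. DNA replication genes were split 16 higher to 14 lower (Pola1 0.18, E2f1 −0.08, Mcm6 −0.18; adjusted p = 0.875). DNA repair genes were split 13 to 13 (Brca1 −0.24, Chek1 0.20, Parp1 0.11, Rad50 0.09; adjusted p = 0.835). Extracellular matrix and contractile genes were split 14 to 14 (Acta2 0.15, Postn 0.16, Thbs1 −0.06, CYR61 0.04; adjusted p = 0.859). Cholesterol synthesis genes lay higher in 15 of 20 cases (Dhcr7 0.11, Mvd 0.14, Lss 0.07; adjusted p = 0.553). For mitosis, DNA replication and integrated stress response genes the median was above 0 and the test pointed down, and for extracellular matrix genes the reverse held.

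Interferon-stimulated genes lay higher in 17 of 27 cases (Gbp2 −0.15, Dhx58 0.21, Oas1a 0.22, Stat2 0.10; camera adjusted p = 0.835). Their medians within pairs were 0.40, −0.10 and −0.13, so the first pair went against the others. Macrophage markers behaved alike, with 13 of 14 higher and pair medians of 0.64, −0.04 and −0.03. Lyz2, the most abundant of them, stood at 53.4 ± 26.2 and 72.3 ± 58.9 CPM (SD, n = 3 each). The macrophage list was not called without the block (adjusted p = 0.553), rose with it (adjusted p = 9.44e-04), was not called there with an estimated correlation (adjusted p = 0.983), and pointed down without replicate 1 (adjusted p = 0.247). Without replicate 1, 27 of 30 ribosome biogenesis genes and 21 of 30 Myc target genes still lay higher, while 25 of 28 mitosis genes and 23 of 27 interferon-stimulated genes lay lower.

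Markers of other cell types gave no call. Endothelial markers were split 3 to 3, with Kdr at 62.1 and 61.5 CPM. Muscle markers were 4 higher and 2 lower, with Des at 37.3 and 35.5 CPM. Neural and glial markers were 2 higher and 5 lower, with Tubb3 at 55.5 and 54.2 CPM. Of 11 listed epithelial markers 4 passed the filter, too few for a list test, and these lay lower, with Krt19 at 81.8 and 79.7 CPM. Of the mitochondrially encoded genes only mt-Co1 was listed, at 5336 ± 160 and 5430 ± 546 CPM (SD, n = 3 each), and of the erythroid markers 0 were listed.

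Replicates differed more than guides. The first principal component held 66.7% of the variance and set both replicate 1 libraries apart, and the second held 20.96% and parted replicate 2 from replicate 3. Levels differed between replicate numbers for 7022 of 14440 genes in limma.

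**Figure D4:**
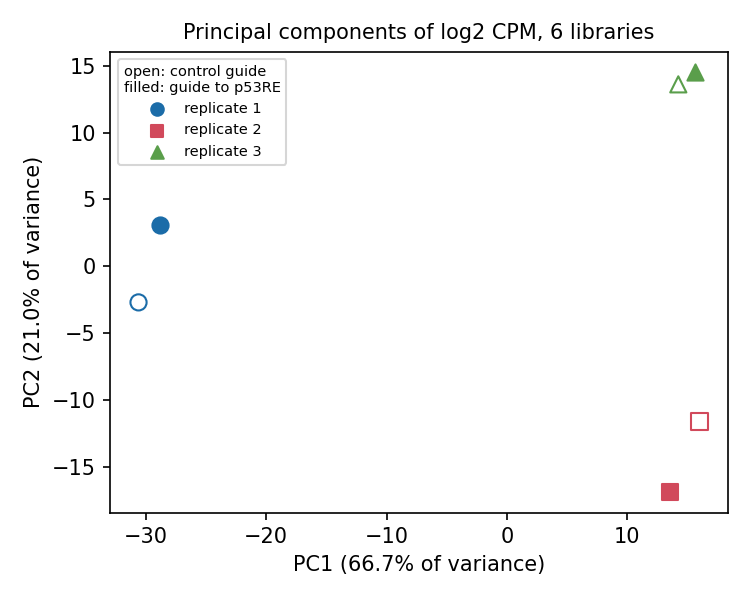
The first and second principal components of log2 CPM for the 6 doxorubicin-treated libraries, with open symbols for the control guide and filled symbols for the guide against the response element. Libraries of equal replicate number lie together, and the first component, with 66.7% of the variance, sets replicate 1 apart.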

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

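DESeq2 and every alternative that combines the replicate block with another choice were chosen after seeing the data, and the others before. Without the block, the count of 0 genes stayed at 0 under every alternative but DESeq2 (1 gene) and the block itself (5). Pvt1 passed with DESeq2 (log2 fold change −1.05, adjusted p = 0.0179) and with the block (−0.999), and Myc with the block (0.67). Over all 16 alternatives Pvt1 lay between −1.16 and −0.85 and Myc between 0.59 and 0.79. The 74 other genes under the naming rule passed in none of 1157 comparisons. The sign of the fold change was less stable, with 52 changes of sign spread over 30 of these genes. Of 144 comparisons of lists, 122 kept their call or their lack of one, and among these were 27 changes of direction without a call.

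The number of genes changed with the replicate block was 5. It was 3 at a threshold of 0.01, 0 at a fold of at least 2, and 0 by limma without trend (Pvt1 −0.999, adjusted p = 0.249; Myc 0.67, adjusted p = 0.835). Without replicate 1, 2 or 3 it was 15, 156 and 8, a range of 8 to 156 that includes the same 5 genes each time. Those fits have fewer residual degrees of freedom than the 2 of the full blocked fit. They also share libraries with it and with each other, so the recurrence of the 5 genes is not an independent check.

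The lists called at the preset correlation, ribosome biogenesis genes and Myc target genes, metabolism and growth, lost the call with an estimated one (adjusted p = 0.971 for both). With the block, inflammatory and secretory genes (0.0243) and macrophage markers (9.44e-04) passed, but not with an estimated correlation too (adjusted p = 0.917 and 0.983). Without a replicate, the blocked inflammatory list ranged from 1.03e-06 to 0.304. Without the block, leaving out single libraries, which breaks the pairs, gave adjusted p of 6.28e-04 to 0.915 for p53 target genes, 4.14e-04 to 0.964 for mitosis genes, 1.75e-05 to 0.346 for Myc target genes, 2.18e-08 to 0.803 for interferon-stimulated genes, 4.14e-04 to 0.947 for inflammatory and secretory genes, 2.33e-07 to 0.672 for cholesterol synthesis genes and 1.75e-05 to 0.915 for macrophage markers. Calls changed without control replicate 1 (p53 target 6.28e-04, mitosis 4.14e-04, Myc target 0.346, inflammatory 4.14e-04, cholesterol 0.00747, macrophage 0.00137), control replicate 3 (p53 target 0.0162, interferon 2.18e-08, cholesterol 2.33e-07), and, of the other guide, replicate 1 (p53 target 0.00795, cholesterol 5.17e-04, macrophage 1.75e-05), 2 (interferon 9.95e-05, macrophage 2.56e-05) and 3 (p53 target 0.00602, mitosis 0.00602, Myc target 0.308, macrophage 0.0161). The p53 target genes pointed up in the first and last of these and down in both others. Cholesterol genes pointed down without control replicate 1, and macrophage markers down without replicate 1 of the other guide.

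In the blocked fit, direction reversed for mitosis genes without replicate 2 (0.00259, range 0.00232 to 0.665), and without replicate 1 for interferon-stimulated genes (2.60e-08, range 2.60e-08 to 0.00845), extracellular matrix and contractile genes (0.00444, range 4.83e-04 to 0.836) and macrophage markers (0.247, range 6.71e-10 to 0.247). The cause was not tested for these reversals or for the losses without trend and with an estimated correlation.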

Other observations

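The tests of ribosome biogenesis genes within pairs 2 and 3, and of where the low genes of replicate 2 lie, were chosen only after the result was seen, and the others before. MEFs of equal replicate number shared large differences from the other replicates under both guides. In both replicate 1 libraries 16 tested genes were at least 4-fold lower than in every other library, among them Has2, a hyaluronan synthase (14.7 and 17.95 CPM against 76.3 to 86.4), and Crabp1, a retinoic acid-binding protein (4.76 and 5.02 CPM against 27.2 to 31.5). In both replicate 3 libraries this held for 1 gene. These genes were chosen after their values were seen.

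In both replicate 2 libraries 3 tested genes were at least 4-fold lower than in every other library, namely Meg3, Rian and Mirg, noncoding genes of the imprinted interval from Dlk1 to Dio3 on chromosome 12 that are expressed from the maternal allele. Meg3 stood at 3.33 and 3.99 CPM in replicate 2 and between 199 and 220 CPM elsewhere, and Rian at 2.60 and 2.83 CPM against 104 to 168. A general loss of imprinted gene expression is argued against, since 0 of 28 measured imprinted genes of other loci were as low. A fault of single genes or their counting met its bound, since only 1 of the 3 other measured genes between Dlk1 and Dio3 was as low, but that bound was badly chosen, because it counted Dlk1 and Dio3, which are expressed from the paternal allele. All 3 low genes lie in the interval and 0 outside it. Mirg stood at 0.0341 and 0.0358 CPM in replicate 2 and between 1.01 and 1.55 CPM elsewhere. Meg3 and Rian prompted that test, so only Mirg, at a low level, adds to it, and a fault of single genes stays open. No biological explanation was tested, since replicate is not a group of the design.

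Ribosome biogenesis genes lay higher with the guide against the response element by a median of 0.08 on the log2 scale. GC content, transcript length and expression level are argued against, since the list median stood at percentile 100 of 10000 lists matched on all 3, whose own median was −0.00. Scaling is argued against by a median of 0.0794 under quantile normalization, lower than under median centring and edgeR scaling. Those other settings could move it little, since the CPM were already scaled and the median over all genes was −3.99e-04. Macrophages are argued against by a median of at least 0.0808 within pairs 2 and 3, where macrophage markers were not higher, while cells of other types stay open. Of the 4 splits that part every pair, only the real one gave a camera p as small as 1.83e-16. The lowest of the others was 6.79e-06, with pair 2 swapped, and these others still hold part of the guide contrast. In any case 4 splits are too few for a share under 0.05. An effect of the guide stays open and was not tested further.

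Macrophage markers were higher by a median of 0.64 in the replicate 1 library with the guide against the response element than in its partner, with Lyz2 at 140 against 83.1 CPM and 32.6 to 44.2 CPM in replicates 2 and 3. The 10668 tested genes between the lowest and highest marker level had a median of 0.00107 in that pair. They made up most of the 14440 tested genes, and CPM are scaled to a common library size. Such a median was therefore likely from the scaling alone, and a shift of low genes stays open. More macrophages in that culture may be a source, since a second list of macrophage genes, fixed before the test, had a median of 0.488, with 14 of 15 tested members higher. No biological explanation from the guide was tested, and the markers were not higher in pairs 2 and 3 (medians −0.04 and −0.03).

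Without the block, 10 of the 10 splits of the 6 libraries gave as many genes as the real guides (0 genes, and 0 at most in any other split), an outcome fixed by the real count of 0, so that this test says nothing. With the block only the real one of the 4 splits that part every pair gave as many (5 genes, and 0 at most in the others), and the splits are too few for a share under 0.05.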
